A study of Mus musculus with 14 samples.

How the data were processed

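Gene expression was measured by RNA sequencing of fibroblasts that had grown out of pieces of mouse lung or dorsal skin and were harvested after 14 days of culture without stimulation. The labels assign 5 libraries to wild-type lung (numbered 1, 23, 3, 4 and 5), 4 to Rel-null lung (7 to 10), 2 to wild-type skin (11 and 22) and 3 to Rel-null skin (18 to 20). Rel encodes c-Rel, a transcription factor of the NF-kappaB family. One Rel-null lung library, number 10, has a treatment label that says skin, whereas its title and source say lung; it was kept with lung, and its Pearson r with the other lung libraries was 0.750 or higher, against at most 0.801 with skin libraries. The numbers are not shared between groups, so no library was paired with another. The labels do not say whether libraries of 1 group came from separate animals, so p-values measure the spread between these libraries.

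The authors deposited raw read counts for 48795 Ensembl genes in all 14 libraries, and every column was matched to a sample. The submitters' processing notes name FastQC 0.11.2, Trimmomatic 0.33, STAR 2.4.2a and the genome build GRCm38, with no role or order. The labels name a directional library kit. The counting tool, its strand setting and the annotation release are not given in the sources used here. Gene symbols and GRCm38 coordinates were taken from GENCODE M21, in which 48435 of the gene identifiers were found and 360 were not. Values of pseudogenes, near-identical gene copies and genes that overlap on opposite strands are uncertain, because it is not known how reads were assigned to them.

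Library totals ran from 12780350 to 30987933 counts, except wild-type skin 22 with 2663437. Intervals on single libraries are exact Poisson intervals at the 95% level on the count. They and the floor of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. Where every library of a group had 0 counts, a fold is given as a bound against 3 counts over that group, from the other group's mean or its pooled counts, whichever is smaller. A gap was a gene at 0 counts whose mean in the other libraries of the same tissue was at least 5 CPM (counts scaled to the library total).

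Genes were tested with edgeR 4.0.16 under R 4.3.3: TMM factors, filterByExpr (minimum count 10, minimum total 15), a quasi-likelihood fit of all 14 libraries with 4 group means, and F tests, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 4 groups shared 1 estimate of spread because wild-type skin has 2 libraries. Where a fit kept 1 library of a skin group, that group had no spread of its own. Of the genes, 16408 were tested, and the common dispersion was 0.948. Comparisons were Rel-null against wild type in lung and in skin, the difference between those effects, and skin against lung within each genotype. Log2 fold changes carry the standard error (SE) of the fit. Group means of named genes are CPM on TMM-scaled totals with the standard deviation (SD); values of single libraries, and the group means of Rel given beside them, are CPM of the raw totals. Genes to name followed a fixed rule based on adjusted p, fold change and level.

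Gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, log2 CPM with a prior count of 1), adjusted over the 29 lists. The pathway lists were collagens, matrix glycoproteins and proteoglycans, matrix remodelling enzymes and inhibitors, contractile myofibroblast genes, the TGF-beta pathway and targets, NF-kappaB family and regulators, NF-kappaB target cytokines and chemokines, interferon-stimulated genes, proliferation, p53 and senescence genes, integrins and adhesion, the Wnt pathway, fibroblast growth factors and receptors, glycolysis and hypoxia, cholesterol synthesis, the unfolded protein response, and MHC class II and antigen presentation. Positional lists covered lung mesenchyme and dermis. Marker lists covered leukocytes and macrophages, lymphocytes, lung epithelium, keratinocytes, endothelium, mesothelium, pericytes, skeletal muscle, adipocytes, and Schwann cells and melanocytes. Groups, tests, lists, the naming rule and a first set of alternatives were fixed before the data were examined. A list's score in a library was the mean log2 CPM of its members, compared between lung groups with a two-sided exact permutation test over 126 splits.

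Alternatives fixed in advance were RLE and upper-quartile factors, no low-count filter, a filter of 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, each library left out in turn, a leukocyte score as covariate, fits of only the groups compared, camera with an estimated correlation, and fry. Chosen after the data were seen were fits without the 4 libraries with the most gaps, without the 2 Xist-positive libraries or without Rel-null skin 19 and 20, fits of 3 against 3 lung libraries, a correction for exon length, the covariate in list tests, and the list tests of the difference between tissues and of Rel-null skin against lung. The method was tested on simulated counts with the same group sizes and spread, in which genes varied independently. Of genes changed 4-fold, it recovered 38% in lung, 18% in skin, 2% for the difference of effects, 16% for the wild-type tissues and 48% for the Rel-null tissues. Recovery at 2-fold was 0%, 2%, 0%, 2% and 0%, and at 16-fold 90%, 48%, 58%, 66% and 64%. The changed genes were drawn from those at 5 CPM or more, so these shares do not cover genes at lower levels. No library was left out of the tests given first. The results of 2 single genes, which stayed in all gene and list tests, are not reported here.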

Results

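The samples were explant cultures of mouse lung and skin fibroblasts, from wild-type mice and from mice labelled as lacking Rel, and the question was how expression differs with the loss of Rel in each tissue. Rel (ENSMUSG00000020275, GRCm38 chromosome 11, 23736847-23770970) was read in libraries of every group. In lung it stood at 9.99 ± 6.32 CPM in wild-type libraries (mean ± SD, n = 5) and at 2.33 ± 1.93 CPM in libraries labelled Rel-null (n = 4), a difference with a two-sided exact permutation p of 0.0794, where 0.00794 is the smallest p the 126 splits allow. The wild-type lung library numbered 4 read 1.10 CPM, below the 4.06, 1.39 and 3.80 CPM of the Rel-null lung libraries numbered 8, 9 and 10. Rel-null lung 7 had 1 Rel count (0.0651 CPM, 95% interval 0.00165 to 0.363). In skin, both wild-type libraries read Rel at 11.2 ± 0.456 CPM. Of the libraries labelled Rel-null skin, number 18 had 1 count (0.0349 CPM), while 19 and 20 read 9.42 CPM (7.97 to 11.1) and 9.47 CPM (7.86 to 11.3), against 11.5 CPM (10.2 to 13) in wild-type skin 11 and 10.9 CPM (7.29 to 15.6) in wild-type skin 22. Both values lie just below the interval of 11 and within that of 22. By edgeR the log2 fold change of Rel was -2.09 ± 1.28 SE in lung (adjusted p = 0.863) and -0.80 ± 1.62 in skin (adjusted p = 0.987), and leaving out Rel-null skin 18 brought the skin value to -0.16. The lowest Rel values were in Rel-null skin 18, Rel-null lung 7 and wild-type lung 4. These libraries were among the 4 with the most gaps (3.37%, 11.5% and 5.78% of expressed genes at 0 counts). Low Rel there was not separated from missing counts and does not by itself bear out a label. Wild-type skin 11, also among the 4 (8.22%), nevertheless read 11.5 CPM. Every direction given for Rel-null cultures follows the labels, which Rel does not bear out for Rel-null skin 19 and 20.

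A pair of genes elsewhere in the genome separated the lung libraries by genotype label. The pair was picked from these data for that separation, which is therefore no independent support for the lung labels. Tpm3-rs7, annotated as protein-coding (ENSMUSG00000058126, chromosome 14, 113314608-113316754), read 33.4 to 71.4 CPM in wild-type lung and 0.781 to 2.00 CPM in Rel-null lung. Rps3a3, a processed pseudogene (ENSMUSG00000059751, chromosome 13, 108670603-108671397), read at most 1.94 CPM in wild-type lung and 70.4 to 295 CPM in Rel-null lung. In skin, Rel-null 18 lay with the Rel-null lung libraries (Rps3a3 332 CPM, Tpm3-rs7 1.71 CPM). Rel-null skin 19 and 20 lay with the wild-type libraries, with Rps3a3 at 1.66 and 0.469 CPM and Tpm3-rs7 at 63.3 and 83.3 CPM. Both genes have close relatives in the genome and their read assignment is uncertain. The series describes the mice as male. Xist, the RNA of the inactive X chromosome, nevertheless read 64.5 CPM in wild-type lung 1 and 732 CPM in wild-type skin 22, where the Y-linked gene Ddx3y had 0 and 3 counts. The other 12 libraries read at most 0.577 CPM of Xist and 34.0 CPM or more of Ddx3y.

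**Figure D1:**
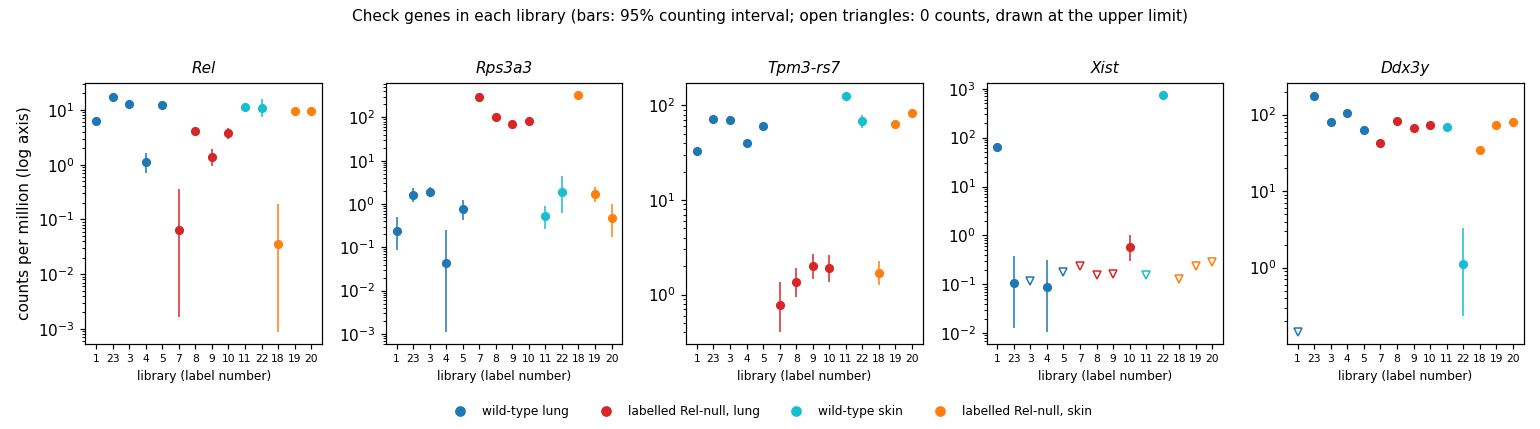
CPM of the raw library total on a log axis for Rel, Rps3a3, Tpm3-rs7, Xist and Ddx3y, with 1 point per library by labelled group, 95% counting intervals, and open triangles at the upper limit where a library had 0 counts. Rel-null skin 19 and 20 sit with the wild-type libraries for Rel (9.42 and 9.47 CPM), Rps3a3 and Tpm3-rs7.

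The share of expressed genes at 0 counts set 4 libraries apart: 11.5% in Rel-null lung 7, 8.22% in wild-type skin 11, 5.78% in wild-type lung 4 and 3.37% in Rel-null skin 18, against at most 0.728% in the other 10. Genes with at least 10 counts ranged from 9826 in Rel-null lung 7 to 14553 in wild-type lung 3. Libraries of 1 group correlated at Pearson r 0.703 to 0.975 across genes, and a lung and a skin library at a median of 0.734. Genes are not independent replicates. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom within a group being 35.3.

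**Figure D2:**
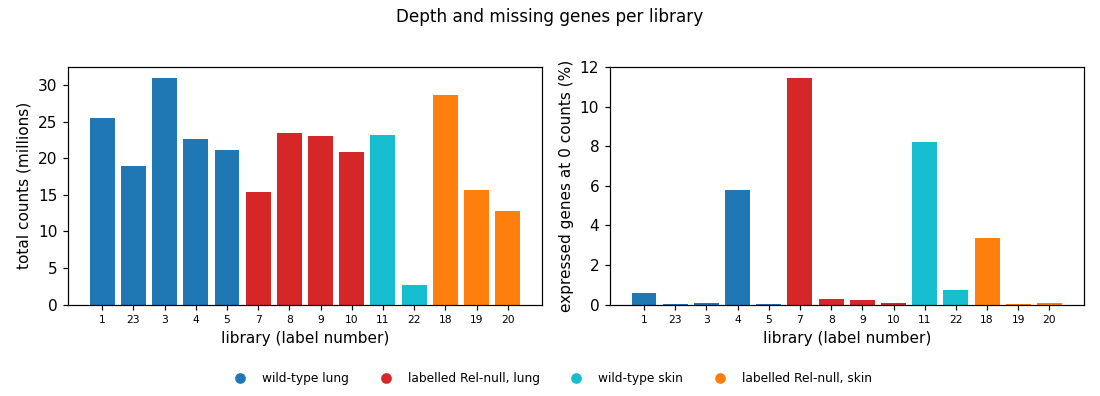
Library totals (left) and the percent of genes expressed in the same tissue that had 0 counts (right), 1 bar per library. Wild-type skin 22 has the lowest total, 2663437 counts, and Rel-null lung 7 the most gaps, 11.5%.

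Collagens and NF-kappaB target cytokines were lower as groups in lung cultures labelled Rel-null (n = 4) than in wild-type ones (n = 5). Of 23 measured collagens, 21 were lower, with a median log2 fold change of -1.16, and the list fell by camera (adjusted p = 1.58e-10, but 0.339 with an estimated correlation). Of 35 cytokine and chemokine genes, 30 were lower, with a median of -1.13 (adjusted p = 1.26e-07, but 0.339 with an estimated correlation). Leukocyte and macrophage markers stood higher at 21 of 26 genes, with a median of 0.65 (adjusted p = 5.93e-06, but 0.507 with an estimated correlation). No single gene passed edgeR's threshold, the smallest adjusted p being 0.173; 1036 genes had an unadjusted p under 0.05, where 820 are expected by chance, while DESeq2 called 65 genes and limma-voom 6.

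Among collagens, 7 of 23 passed when adjusted over the list alone, and 9 had an unadjusted p under 0.05, all of them lower. Col11a1, a minor fibrillar collagen (ENSMUSG00000027966, chromosome 3, 114030540-114220718), read 123 ± 21.4 CPM in wild-type and 41.7 ± 7.39 CPM in Rel-null lung (log2 fold change -1.55 ± 0.31 SE, adjusted p = 0.735). Col12a1, which lies on the surface of collagen fibrils, read 1180 ± 924 and 205 ± 127 CPM (-2.53 ± 0.56, adjusted p = 0.781). The main fibrillar collagens had smaller values with wide error, -0.90 ± 0.66 for Col1a1 and -0.72 ± 0.72 for Col3a1. Matrix remodelling enzymes and inhibitors fell with 36 of 41 genes lower (median -0.57, adjusted p = 8.42e-08, 0.339 with an estimated correlation), among them the cross-linking enzyme Lox at -0.82 ± 0.35, and 0 passed when adjusted over the list alone. Matrix glycoproteins and proteoglycans fell with 32 of 41 lower (median -0.55, adjusted p = 1.23e-04, 0.726 with an estimated correlation) and 1 past the threshold when adjusted over the list alone. Fibronectin, Fn1, read 11742 ± 3361 CPM in wild-type and 4607 ± 3809 CPM in Rel-null lung (-1.35 ± 0.54). Without wild-type lung 1, an Xist-positive library, the median of collagens was -0.75 and that of glycoproteins -0.18, both still past camera's threshold, and the glycoprotein call ended without both Xist-positive libraries (adjusted p 0.0645).

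Of the NF-kappaB targets, 2 passed when adjusted over the list alone. Lif, a cytokine of the interleukin 6 family, read 65.7 ± 54.8 CPM in wild-type and 3.50 ± 1.96 CPM in Rel-null lung (log2 fold change -4.22 ± 0.94, adjusted p = 0.781), and the macrophage growth factor Csf1 had a value of -1.20 ± 0.65. Without wild-type lung 4 the list's median was -0.73. Interferon-stimulated genes fell with 32 of 36 lower (median -0.79, adjusted p = 0.00143, 0.726 with an estimated correlation), growth factors and receptors with 27 of 35 lower (-0.52, 0.00310, 0.339), and glycolysis and hypoxia genes with 25 of 31 lower (-0.29, 0.0137, 0.448). Cholesterol synthesis genes rose with 16 of 24 higher (0.19, 0.0302, 0.726). Adjusted over the list alone, 0 genes passed among interferon-stimulated genes, growth factors and the leukocyte list, where Mpeg1 and Lyz2, genes of macrophages, had log2 fold changes of 0.71 ± 0.46 and 0.27 ± 0.48. No lung call holds with an estimated correlation, and fry called 0 lists. Single libraries decided the smaller values: the interferon median was -0.48 without wild-type lung 23 and -0.43, no longer called, without the 4 libraries with the most gaps, and the glycolysis call ended without wild-type lung 4 (-0.22), with a median of -0.18 without Rel-null lung 7. Without the 4 libraries with the most gaps the calls of glycolysis (-0.12) and cholesterol genes (0.06) ended as well. The cholesterol call ended without wild-type lung 23 (0.11), wild-type lung 4 (0.07), Rel-null lung 7 (0.17) or Rel-null lung 9 (0.22), and the median was 0.37 without wild-type lung 1 and 0.28 without Rel-null lung 8.

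In exact permutation tests of list scores, in log2 CPM per library, matrix remodelling genes (7.73 ± 0.17 in wild-type and 6.87 ± 0.52 in Rel-null lung) and glycolysis genes (7.29 ± 0.11 and 6.87 ± 0.44) did not overlap between groups, with the smallest p possible, 0.00794. The exact p was 0.0159 for NF-kappaB targets (4.16 ± 0.78 and 2.52 ± 0.95) and 0.0238 for collagens (7.51 ± 0.57 and 6.30 ± 0.71). NF-kappaB targets did not overlap either, but narrowly (wild-type 3.25 or higher, Rel-null at most 3.23). Rel-null lung 7, the library with the most gaps, had the lowest Rel-null lung score in each of these lists. Its glycolysis score was 6.22, and the other Rel-null lung libraries, at 7.04 to 7.13, lay close to the wild-type minimum of 7.20. Low scores in Rel-null lung 7 were not separated from missing counts. The other lists called by camera in lung showed no clear difference between libraries. Their exact p was 0.119 for interferon-stimulated genes, 0.206 for growth factors, 0.373 for matrix glycoproteins, 0.413 for leukocyte markers and 0.913 for cholesterol genes. Adjusted over the 29 lists the lowest value was 0.115. The other 20 lists did not pass camera in lung. Their medians were 0.20 for contractile genes, -0.02 for the TGF-beta pathway, -0.21 for the NF-kappaB family, -0.27 for proliferation, 0.11 for p53 genes, -0.12 for integrins, 0.06 for the Wnt pathway, -0.19 for the unfolded protein response and 0.34 for MHC class II. The contractile value rested on Rel-null lung 7, with a score of 8.56 against 6.42 to 6.98 in the other Rel-null lung libraries. Without it camera called the list lower (median -0.49, adjusted p = 9.11e-06). Positional and marker lists had medians of -0.28 for lung mesenchyme, 0.00 for dermis, 0.80 for lymphocytes, -1.30 for lung epithelium, 0.00 for keratinocytes, -0.51 for endothelium, 0.66 for mesothelium, -0.13 for pericytes, 0.00 for skeletal muscle, -0.08 for adipocytes and -0.09 for Schwann cells and melanocytes, where the test pointed upwards. Other single genes with small p-values were the processed pseudogene Gm8210 (9.79 ± 1.96, adjusted p = 0.735), the skeletal actin Acta1 (8.11 ± 1.88, 78.3 ± 154 CPM in Rel-null lung), the scaffold protein Akap12 (-1.83 ± 0.42), Uaca (-1.57 ± 0.36) and the adiponectin receptor Adipor1 (0.91 ± 0.23), the last 4 at an adjusted p of 0.781.

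**Figure D3:**
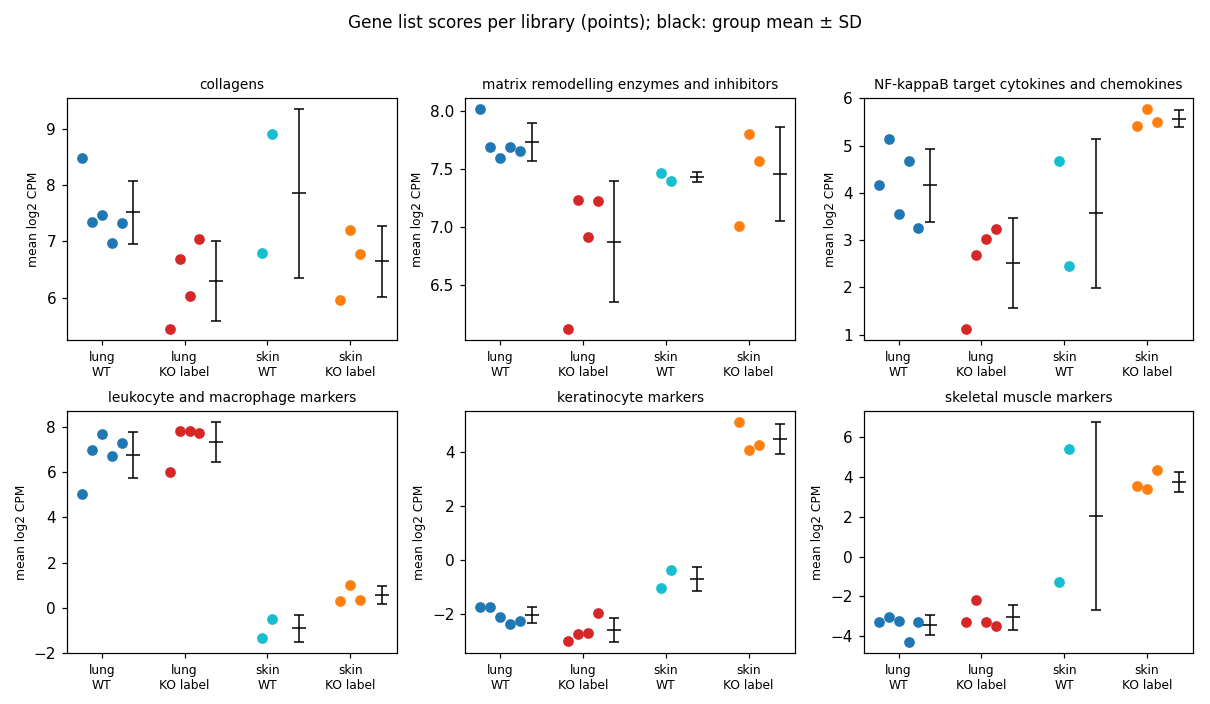
List scores (mean log2 CPM of a list's genes) for 6 lists, with 1 point per library by labelled group and black marks for the mean ± SD. Keratinocyte scores of the 3 skin libraries labelled Rel-null lie at 4.09 to 5.12, above every other library, and Rel reads in 2 of those libraries, 19 and 20, are near the wild-type level.

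Keratinocyte genes were higher in skin cultures labelled Rel-null (n = 3) than in wild-type ones (n = 2): 18 of 19 measured genes, with a median log2 fold change of 5.46. The list rose by camera (adjusted p = 2.46e-20), with an estimated correlation (adjusted p = 0.00194) and by fry (adjusted p = 1.05e-04), and with genes at 0 counts in a group set to their bound the median was 5.18. Adjusted over the list alone, 11 of the 19 genes passed. The basal keratin Krt5 (ENSMUSG00000061527, chromosome 15, 101707070-101712898) read 0.671 ± 0.409 CPM in wild-type and 234 ± 158 CPM in Rel-null skin (log2 fold change 8.75 ± 0.96, edgeR adjusted p = 0.0513), and its partner Krt14 15.3 ± 19.0 and 709 ± 487 CPM (5.46 ± 0.99, adjusted p = 0.140). Krt17 read 1.55 ± 0.383 and 316 ± 62.8 CPM (7.59 ± 1.52), and the simple-epithelium keratin Krt8 6.68 ± 8.54 and 305 ± 101 CPM (5.39 ± 1.14), both at an adjusted p of 0.216.

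No single gene passed edgeR's threshold in skin either: 1024 had an unadjusted p under 0.05, where 820 are expected, while DESeq2 called 194 and limma-voom 300. Without wild-type skin 22, the library with the fewest counts, edgeR called 421 genes. Beside Krt5, the genes at an adjusted p of 0.0513 were Clu, encoding the secreted chaperone clusterin (36.9 ± 39.5 CPM in wild-type and 2808 ± 756 in Rel-null skin, 6.23 ± 0.96), the protease inhibitor Spint2 (8.10 ± 1.32), the fungal receptor Clec7a (0 counts in wild-type and 3.78 ± 2.12 CPM in Rel-null skin, at least 33.7-fold higher), and the lipase Mgll (-3.30 ± 0.54). The plasminogen activator Plau (3.16 ± 0.54) and Sema4a (8.04 ± 1.38) stood at 0.0654. Apolipoprotein Apoc1, at 3.71 ± 4.34 CPM in wild-type and 0 counts in Rel-null skin, was at least 74.3-fold lower (adjusted p = 0.0966). Other lower values were -1.50 ± 0.32 for Abcc5, -6.63 ± 1.40 for Lrg1 and -1.75 ± 0.36 for Txndc16, at an adjusted p of 0.216, and -6.49 ± 1.42 for the cytokine receptor Il21r, at 0.238.

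Collagens fell in Rel-null skin with 21 of 23 genes lower (median log2 fold change -1.66, camera adjusted p = 6.54e-11, adjusted p = 0.395 with an estimated correlation), and 9 passed when adjusted over the list alone; Col3a1 read 3192 ± 3266 and 752 ± 638 CPM (-2.09 ± 0.97). Without wild-type skin 22 the collagen median was -0.12 and the call ended. All 6 adipocyte markers were lower and passed when adjusted over the list alone (median -2.55, adjusted p = 1.82e-06, 0.216 with an estimated correlation), among them the lipid carrier Fabp4 (-3.62 ± 1.02) and the lipase Lpl (-2.34 ± 0.71). That call ended without wild-type skin 11, with a median of -0.23. Matrix glycoproteins fell with 25 of 41 lower (-0.39, 0.0329, 0.881 with an estimated correlation), and the call ended without wild-type skin 11 (-0.26), wild-type skin 22 (-0.11) or Rel-null skin 18 (-0.04), while the median was -0.72 without Rel-null skin 19 and -1.19 without 19 and 20. Fn1 had a log2 fold change of -1.85 ± 0.71.

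Of the other lists that rose in Rel-null skin by camera, none held with an estimated correlation. Parentheses give the median, camera's adjusted p and the adjusted p with an estimated correlation. Leukocyte markers were higher at 19 of 26 genes (median 0.94, or 0.88 with bounds, adjusted p = 8.71e-06, 0.407 with an estimated correlation), at low levels, Mpeg1 reading 2.30 ± 2.18 and 7.17 ± 2.48 CPM. NF-kappaB targets were higher at 27 of 35 (0.68, 5.57e-05, 0.407), proliferation genes at 34 of 40 (0.76, 1.77e-04, 0.416), for example Pcna at 1.19 ± 0.48, and cholesterol synthesis genes at 21 of 24 (0.74, 1.77e-04, 0.498). Lung epithelial markers, which include the simple keratin Krt8, were higher at 10 of 19 (0.29, 0.00400, 0.407), p53 and senescence genes at 16 of 21 (0.43, 0.0147, 0.407), and glycolysis genes at 20 of 31 (0.45, 0.0191, 0.407). Wild-type skin 22 and 11 weighed on all of these but proliferation. Without 22 the median was 0.00 for NF-kappaB targets, 0.42 for cholesterol, 0.16 for lung epithelium and 0.32 for glycolysis, each no longer called, and 3.34 for leukocyte markers. Without 11 it was 3.49 for NF-kappaB targets, 1.37 for cholesterol, 1.68 for lung epithelium and 2.08 for leukocyte markers, and the p53 call ended (0.50). Shifts also came from Rel-null skin 18 (lung epithelium 0.00), 19 (cholesterol 0.42) and 20 (p53 genes 0.24), and the lung epithelial median was 0.47 without either wild-type lung 23 or 3. Without Rel-null skin 19 and 20, Rel-null skin was library 18 alone, with no spread of its own. The calls of cholesterol (-0.13), p53 (0.15) and glycolysis genes (0.44) then ended. The median was 0.27 for leukocyte markers, 0.42 for NF-kappaB targets and 0.00 for lung epithelium. Without the Xist-positive libraries, which left wild-type skin as library 11 alone, the proliferation call ended (median 0.97).

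The remaining 18 lists did not pass in skin. Medians were -0.20 for matrix remodelling, 0.22 for contractile genes, 0.11 for the TGF-beta pathway, where the test pointed downwards, -0.08 for the NF-kappaB family, 0.10 for interferon-stimulated genes, -0.14 for integrins, 0.64 for the Wnt pathway, 0.15 for growth factors, 0.18 for the unfolded protein response and 0.56 for MHC class II. They were 0.00 for lung mesenchyme and lymphocytes, -0.00 for dermis, 0.47 for endothelium, 0.33 for mesothelium, -0.69 for pericytes, -2.42 for Schwann cells and melanocytes, and -0.43 for skeletal muscle, where the test pointed upwards. Skeletal muscle scores in wild-type skin were apart, -1.29 in library 11 and 5.37 in library 22, with 3.74 ± 0.51 in Rel-null skin.

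The effect of the Rel-null label differed between skin and lung for 6 lists by camera, and for 0 with an estimated correlation. NF-kappaB targets had a difference of effects of 1.70 (median log2, skin minus lung, camera adjusted p = 1.91e-12, but 0.140 with an estimated correlation), with 32 of 35 genes on the skin side. With the same values in parentheses, keratinocyte genes had 6.74 (4.06e-05, 0.140), proliferation genes 1.07 (5.35e-06, 0.352), glycolysis genes 0.60 (1.04e-04, 0.145), lung epithelial markers 2.91 (0.00707, 0.50) and adipocyte markers -2.81 (1.58e-05, 0.145). Fry called NF-kappaB targets (0.0492), glycolysis (0.0490) and keratinocytes (0.0133). Without wild-type skin 22 the calls of NF-kappaB targets (1.07), keratinocytes (7.59) and lung epithelium (3.69) ended, without 11 that of adipocytes (-0.31), and without Rel-null skin 18 that of lung epithelium (2.83). Without 11 the NF-kappaB median was 4.66. Without Rel-null skin 19 and 20, which left library 18 alone, the calls of lung epithelium (2.82) and adipocytes (-3.99) ended.

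For collagens the difference of effects was -0.26 (adjusted p = 0.137), so a different response of collagens in skin and lung was not shown. No gene passed edgeR's threshold for the difference, with 766 at an unadjusted p under 0.05 (820 expected); DESeq2 called 101, limma-voom 174, and edgeR 370 without wild-type skin 22. The smallest adjusted p was 0.101, for Clu (6.41 ± 1.05), Spint2 (8.60 ± 1.42) and Clec7a, the last at 0 counts in wild-type skin. Plau (3.38 ± 0.62) stood at 0.166, as did Krt17 and Apoc1, each with a group at 0 counts, Mgll (-3.17 ± 0.65) at 0.236, Lrg1 (-7.51 ± 1.59) at 0.310, the glycolytic regulator Pfkfb4 (-2.85 ± 0.65) at 0.452 and Il21r (-6.77 ± 1.60) at 0.496. Across all tested genes the effects in lung and skin correlated at r = 0.0740, and of 105 genes with an unadjusted p under 0.05 in both, 83 had the same sign. Genes are not independent replicates.

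Between wild-type skin (n = 2) and wild-type lung (n = 5), 148 genes were higher and 339 lower in skin by edgeR, 487 in all and each by more than 2-fold. DESeq2 called 1314, limma-voom called 661 but shared only 147 of the 487, and edgeR called 258 without wild-type skin 11, 1050 without 22, 317 without wild-type lung 3, 828 without Rel-null lung 7 and 0 with a leukocyte score as covariate, which nearly follows tissue (1435 at an unadjusted p under 0.05). All 26 leukocyte and macrophage markers were lower in skin, 20 of them past the threshold and 25 when adjusted over the list alone, with a median log2 fold change of -8.72, or -8.50 with genes at 0 set to their bound (camera adjusted p = 5.94e-62, 0.00707 with an estimated correlation). Mpeg1, a pore-forming protein of macrophages (ENSMUSG00000046805, chromosome 19, 12460779-12465283), read 1484 ± 621 CPM in lung and 2.30 ± 2.18 CPM in skin (-9.65 ± 1.00, adjusted p = 1.45e-04). The lysosomal protein Cd68 (-6.50 ± 0.69) and the Fc receptor Fcgr3 (-8.16 ± 0.87) were at the same adjusted p, and Clec7a, at 121 ± 35.6 CPM in lung and 0 counts in skin, was at least 1076-fold lower. Also at 0 counts in skin were Fcrls (at least 1095-fold lower), Tnfsf8 (977-fold), Rac2 (778-fold), Selplg (596-fold), Cd52 (565-fold), Nfam1 (544-fold) and Cd300ld (436-fold); Rac2 and Cd300ld lost the call without wild-type skin 11 (adjusted p 0.0635 and 0.0978).

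Positional genes followed the tissue of origin. Of 27 dermal genes, 23 were higher in skin, 6 past the threshold and 12 when adjusted over the list alone (median 2.91, adjusted p = 1.42e-13, 0.00707 with an estimated correlation), though the median was 0.59 without wild-type skin 22. Hoxc9, a homeobox gene of the body axis (ENSMUSG00000036139, chromosome 15, 102976439-102985099), had 0 counts in wild-type lung and 30.2 ± 20.1 CPM in skin, at least 1138-fold higher. Hoxc8 (10.81 ± 1.45, adjusted p = 6.24e-04) and Zic1 (9.27 ± 1.46, 0.00344) were also higher. Lung mesenchyme genes fell with 19 of 21 lower, 10 when adjusted over the list alone (median -3.33, 1.56e-07, 0.145 with an estimated correlation, -8.60 without wild-type skin 22). Among them, Tcf21, of the embryonic lung mesenchyme (-8.87 ± 1.58, 0.00626), lost the call without wild-type skin 11 (adjusted p 0.0792), and Gata6 (-3.33 ± 0.67) without 22 (0.0548).

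Glycolysis genes were lower in wild-type skin at 28 of 31, 16 when adjusted over the list alone (median -1.20, adjusted p = 6.72e-10, 0.0203 with an estimated correlation), among them Pfkl, the liver phosphofructokinase (-1.72 ± 0.31, adjusted p 0.0626 without wild-type skin 11). The growth factor Igf1 read 542 ± 97.5 CPM in lung and 20.7 ± 6.13 CPM in skin (-4.70 ± 0.67, adjusted p = 9.98e-04), and Igfbp4 (-6.55 ± 1.02), Vegfd (-2.90 ± 0.49), the Wnt agonist Rspo3 (-5.48 ± 0.67), myosin light chain kinase Mylk (-5.06 ± 0.76) and the adhesion molecule Icam1 (-3.88 ± 0.43) were lower as well. Of matrix genes, Col15a1 (4.34 ± 0.69) was higher in skin, while the basement membrane protein Nid2 (-3.11 ± 0.57) and the lysyl hydroxylase Plod2 (-3.11 ± 0.51, adjusted p 0.0507 without wild-type skin 11) were lower. Periostin, Postn (5.07 ± 0.77), and Col6a3 (4.02 ± 0.86) were called higher, with values of 2.16 and 1.86 and no call without wild-type skin 22. The prolactin-family gene Prl2c3, at 163 ± 22.6 CPM in skin and 0.0206 ± 0.0461 CPM in lung, had the smallest adjusted p (12.71 ± 0.84, 2.59e-05).

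Markers of other cells also differed between the wild-type tissues, with the median, adjusted p and adjusted p with an estimated correlation in parentheses. All 23 skeletal muscle markers were higher in skin, 13 past the threshold and 22 when adjusted over the list alone (median 9.64, or 8.47 with bounds, adjusted p = 6.32e-18, 0.139 with an estimated correlation). The myosin light chain Myl1 was at least 1274-fold higher, and titin, Ttn (9.85 ± 1.36), and troponin Tnnc2 (9.20 ± 1.35) were higher too. Without wild-type skin 22 the muscle median was 0.00. Keratinocyte markers were higher in wild-type skin than in lung (median 0.62, adjusted p = 4.61e-05, 0.0433 with an estimated correlation), for example Krt14 (10.05 ± 1.03). The median was 0.00 without wild-type skin 22 and 1.33 to 2.03 without wild-type lung 1 or any 1 library of Rel-null skin. Cholesterol synthesis (0.61, 4.98e-05, 0.425), integrins (0.25, 0.00386, 0.322) and Schwann cell and melanocyte markers (3.51, 0.00945, 0.462) were called higher. The cholesterol call ended without wild-type skin 11 (0.02, 0.92 without 22), and those of integrins (-0.12) and Schwann cells (-1.41) without 22. The integrin median was 0.62 without 11, 0.40 without wild-type lung 1 and 0.42 without wild-type lung 5. MHC class II (-2.28, or -2.01 with bounds, 9.57e-05, 0.322), interferon-stimulated genes (-1.58, 2.03e-04, 0.481) and endothelial markers (-5.73, or -4.34, 4.80e-04, 0.340) were lower. Without wild-type skin 22 the interferon median was -4.84 and the endothelial one -9.59, and the endothelial call ended without both Xist-positive libraries (-8.68, adjusted p 0.0850). The nerve growth factor receptor Ngfr turned from 11.88 ± 2.05 to -3.20 without 22.

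Between skin (n = 3) and lung (n = 4) cultures labelled Rel-null, edgeR called 299 genes higher and 530 lower in skin, 829 in all, 824 of them by more than 2-fold. DESeq2 called 1939 and limma-voom 4501, and edgeR 513, 496 and 410 without Rel-null skin 18, 19 or 20, 1323 and 550 without Rel-null lung 7 or 8, 409 without Rel-null skin 19 and 20, and 0 with the leukocyte covariate (1431 at an unadjusted p under 0.05). Keratinocyte markers were higher at 19 of 19 genes, 9 past the threshold and 17 when adjusted over the list alone (median 9.73, or 7.36 with bounds, camera adjusted p = 2.45e-25, 4.35e-04 with an estimated correlation). Krt14, Krt17, Krt5 and Krt6a had 0 counts in all 4 Rel-null lung libraries and were at least 18933-fold, 8447-fold, 6244-fold and 4713-fold higher. Leukocyte markers were lower at 26 of 26 genes, 22 past the threshold and 25 when adjusted over the list alone (median -6.65, 7.45e-63, 0.00459), with Mpeg1 at -8.40 ± 0.77 (adjusted p = 1.85e-05), Cd68 at -6.58 ± 0.57 and the Fc receptor Fcgr1 at -11.15 ± 1.07. The macrophage genes Fcrls (at least 7898-fold lower), Chil3 (2866-fold), Marco (1992-fold), Aoah (1746-fold), Ly86 (1417-fold), Cd5l (1360-fold) and Ms4a6c (1271-fold) had 0 counts in Rel-null skin. Without Rel-null skin 19 and 20, which left library 18 alone, Chil3 and Marco lost the call.

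Parentheses again give the median and both adjusted p-values. Dermal positional genes were higher in Rel-null skin (median 2.66, adjusted p = 1.07e-08, 0.0625 with an estimated correlation), led by Twist2 (7.54 ± 1.18), Crabp1 (6.92 ± 1.17) and Zic1 (0 counts in lung, at least 645-fold), and lung mesenchyme genes were lower (-2.46, 1.29e-05, 0.269), with Tcf21 at least 346-fold and Tbx4 at -5.43 ± 1.26 (adjusted p 0.0921 without Rel-null skin 19). NF-kappaB targets were higher (3.12, or 2.87 with bounds, 3.85e-08, 0.231), 11 past the threshold upwards and 1 downwards, for example the neutrophil chemokine Cxcl5 (48.0 ± 28.8 CPM in lung and 2233 ± 1281 CPM in skin, 5.54 ± 0.99) and Lif (5.77 ± 1.05), against Icam1 (-2.36 ± 0.33). Of matrix genes, tenascin Tnc (3.80 ± 0.47), Thbs2 (3.18 ± 0.54) and Col12a1 (2.85 ± 0.61) were higher and Col14a1 (-4.45 ± 0.75), Col3a1 (-4.72 ± 1.00) and Ogn (-4.61 ± 0.78) lower, Col3a1 losing its call without Rel-null skin 18 (adjusted p 0.0501) or 20 (0.0744). Without both 19 and 20, which left Rel-null skin as library 18 alone, the calls of Cxcl5 (4.16), Col12a1 (2.17) and Col3a1 (-6.92) ended. Skeletal muscle markers (7.09, or 6.51, 1.09e-15, 0.127 with an estimated correlation), cholesterol synthesis (1.20, 1.30e-08, 0.269), proliferation (0.75, 2.19e-04, 0.356), integrins (0.30, 0.00499, 0.286) and p53 genes (0.27, 0.0471, 0.373) were higher. MHC class II (-1.04, 0.00203, 0.385), glycolysis (-0.48, 0.00646, 0.286) and endothelial markers (-3.96, or -3.50, 0.0295, 0.521) were lower.

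The smaller of these list calls rested on few libraries. The p53 call ended without wild-type lung 1 (0.26) or 4 (0.26), Rel-null lung 8 (0.12) or 10 (0.16), or Rel-null skin 20 (0.25), and the endothelial call without wild-type lung 1 (-3.97), Rel-null lung 10 (-2.12) or Rel-null skin 19 (-5.75). Proliferation stood at 0.49 without Rel-null lung 8, integrins at 0.63 without 7 and 0.20 without 9, and p53 genes at 0.67 without 7. Without Rel-null skin 19 and 20, whose label Rel does not bear out, the calls of MHC class II (-1.18), glycolysis (-0.29), endothelium (-8.42), integrins (0.09) and p53 genes (0.22) ended, and the medians of cholesterol synthesis and dermal genes were 0.59 and 1.66. Of the calls made in both genotypes, 99 higher in skin were shared (2.7 expected of independent lists) and 261 lower (10.9 expected), and 1 gene was called in opposite directions. Igf1 (-5.43 ± 0.58), Igfbp4 (-5.81 ± 0.82), Mylk (-4.75 ± 0.62) and Plod2 (-3.26 ± 0.43) were lower in Rel-null skin as in wild-type skin.

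**Figure D4:**
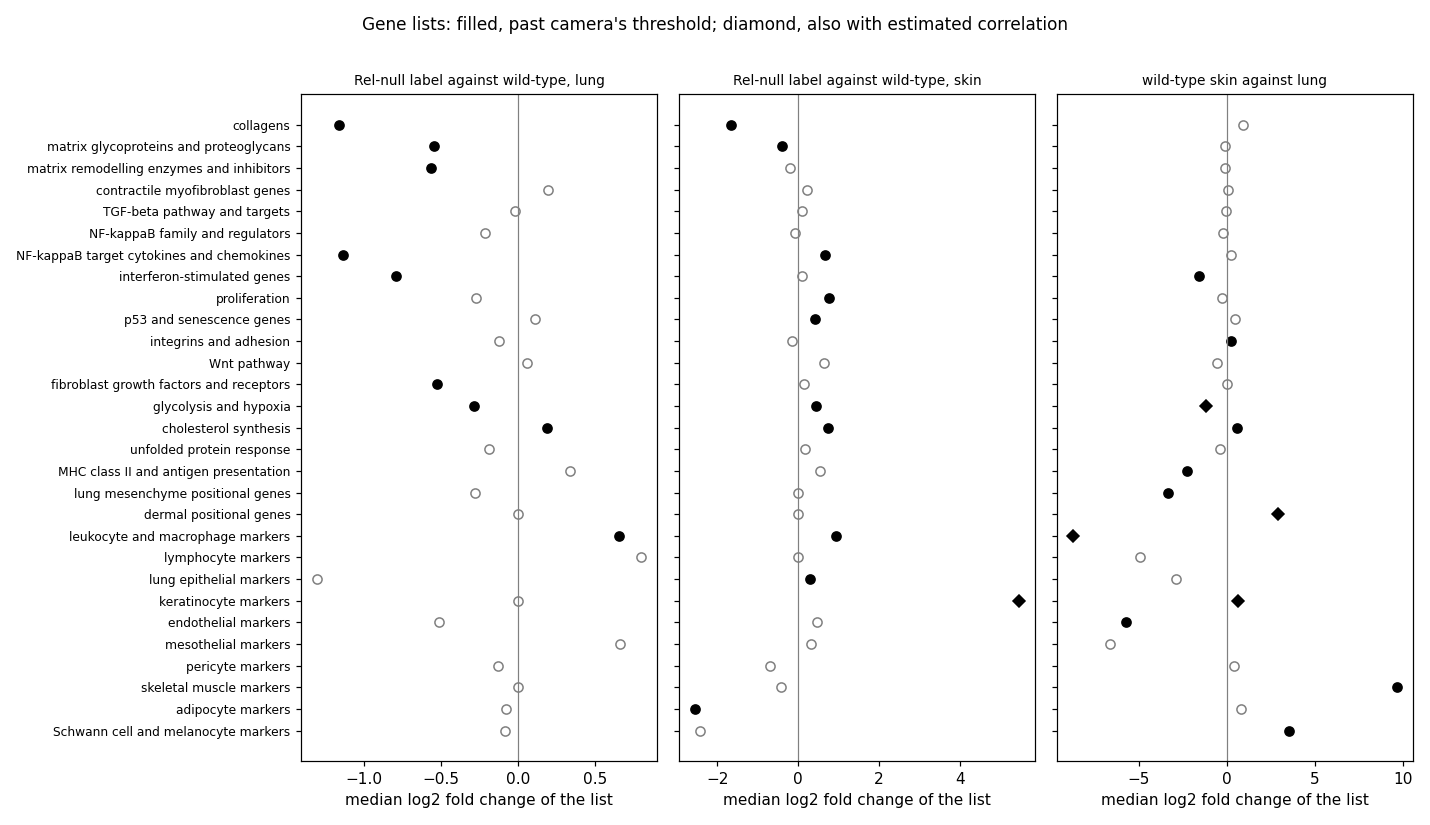
Median log2 fold change of each of the 29 lists for Rel-null against wild-type lung, Rel-null against wild-type skin (both by label) and wild-type skin against wild-type lung, filled where camera's adjusted p passed the threshold and a diamond where it also passed with an estimated correlation. Diamonds are the keratinocyte list in skin by genotype (5.46) and 4 lists between the wild-type tissues, among them leukocyte markers (-8.72).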

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

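Single libraries far from the rest of their group were looked for in 82 groups of values; 15 were found, where 4.1 are expected by chance. The list tests of the difference between tissues, the covariate and exon length tests of collagens, the tests of keratinocyte genes, and the test of whether Rel-null skin 19 and 20 lack Rel, were chosen only after those results were seen.

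Wild-type lung 4 and Rel-null lung 7 stood apart in the share of expressed genes at 0 counts, 5.78% (0.0188% to 0.605% in the others of the group) and 11.5% (0.102% to 0.270%). Both also had low list scores. In wild-type lung 4, proliferation scored 3.36 (others 4.18 to 4.36), integrins 4.41 (5.59 to 5.92), growth factors 4.81 (5.86 to 6.26) and skeletal muscle -4.28 (-3.28 to -3.04). In Rel-null lung 7, the NF-kappaB family scored 2.00 (4.44 to 4.84), glycolysis 6.22 (7.04 to 7.13) and leukocyte markers 6.03 (7.73 to 7.82), and Rps3a3 read 295 CPM (70.4 to 104). Wild-type lung 1 stood apart in Xist, 64.5 CPM (0 to 0.106), and in matrix remodelling, 8.02 (7.60 to 7.70). Rel-null lung 10 had Xist at 0.577 CPM (0 in the others), wild-type lung 23 had a glycolysis score of 7.48 (7.20 to 7.28), and Rel-null lung 8 a skeletal muscle score of -2.15 (-3.48 to -3.26).

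The effect of the Rel-null label differed between skin and lung, by camera on the difference of effects, for NF-kappaB targets (median 1.70), proliferation (1.07), glycolysis (0.60), lung epithelial markers (2.91), keratinocyte markers (6.74) and adipocyte markers (-2.81). None of these calls holds with an estimated correlation (adjusted p 0.140 to 0.50), and those of NF-kappaB targets (1.07), keratinocytes (7.59) and lung epithelium (3.69) end without wild-type skin 22, and that of adipocytes (-0.31) without 11.

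Rel reads in libraries labelled Rel-null were weighed first. A segment of another strain carried along with the targeted allele could shift genes near Rel. Its test bears on those genes and not on the source of the Rel reads. Of 87 genes within 10 Mb, the odds of an unadjusted p under 0.05 were 0.714 times those elsewhere in lung (95% interval 0.190 to 1.90). In skin they were 0.916 times (0.289 to 2.23). Equal or lower odds had been set before the test to speak against a segment. Both intervals also hold higher odds, which leaves a segment open. Whether skin 19 and 20 are not Rel-null stayed open too. Both lay on the wild-type side for 100% of the 2 genes that part the lung genotypes most clearly, Rps3a3 and Tpm3-rs7, which had been seen before the test. For 65 genes chosen more widely the shares were 63.1% and 61.5%, against 44.6% in skin 18, but wild-type skin 11 itself reached only 55.4%, and 22 reached 84.6%.

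Lower collagens in Rel-null lung were weighed next (median -1.16). With the leukocyte score as a covariate the median was -1.03, or 88.3% of its size. That share lay above the mark set before the test to speak against leukocytes. With the SE over collagen genes, 0.20, allowed for, it fell under the mark. Without the Xist-positive wild-type lung 1 the median was -0.75 (64.8%). Leukocyte share and that library could each account for a part, and both stay open. Removing the trend with exon length across all genes gave -1.19 (102%) and moved no list median by more than 0.034. These values argue against a trend with exon length across all genes as the source of the lower collagens. Of 100 splits of the 9 lung libraries, the real one included, 45 gave at least as many called lists (9 with the real labels, 18 in the highest other split). Chance is therefore not excluded for the lung lists. For single genes the splits decide nothing, since the real count is 0 and all 100 of 100 must reach it (highest other 5). An effect of Rel was not separated from leukocyte share, wild-type lung 1 or chance.

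Keratinocyte genes in Rel-null skin were weighed last. Low depth of wild-type skin 22 is unlikely to explain them. With Rel-null skin thinned to its 2663437 counts, 15 of 19 markers (78.9%) stayed higher in all 3 libraries. The exact 95% interval, 54.4% to 93.9%, treats the markers as independent, which they are not. Thinning does not imitate the gaps of wild-type skin 11, where 8.22% of expressed genes had 0 counts. Keratinocytes growing in the cultures would raise most markers together. Of 19 measured markers, 16 were higher in all 3, where chance gives 10% per gene. These were the same 16 of 16 (100%) that had a mean of at least 5 CPM in either skin group. A marker can pass that filter through its high values in Rel-null skin alone. Both counts nearly restate the pattern and decide nothing. Loss of Rel stayed open, since skin 19 and 20, with Rel near the wild-type level, scored 4.09 and 4.28, nearer to the 5.12 of skin 18 than to the wild-type mean of -0.70, while their genotype is in doubt.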

How the results depend on the processing

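The fits without the libraries with the most gaps, without the Xist-positive ones, without Rel-null skin 19 and 20 and with 3 against 3 lung libraries, the covariate in list tests, and list tests for the difference and the Rel-null tissues were chosen only after results were seen. No paired analysis was possible because no label ties a lung culture to a skin culture or a wild-type culture to a Rel-null one. Counts are given in the order lung by genotype, skin by genotype, difference of effects, wild-type skin against lung, and Rel-null skin against lung, where edgeR called 0, 0, 0, 487 and 829 genes. RLE factors kept all of them within 1.5 times (0, 0, 0, 492 and 857). The cause of the changes below was not tested, except that fewer libraries or genes entered where some were left out; where wild-type skin kept 1 library, that library is assumed to vary like the others.

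Upper-quartile factors gave 3 genes in skin. Without the low-count filter there were 5, 58, 31 and 782 in the first 4 comparisons. DESeq2 called 65, 194, 101, 1314 and 1939, and limma-voom 6, 300, 174, 661 (sharing 147 of the 487) and 4501. With the leukocyte score as a covariate, which nearly follows tissue, the difference of effects had 2 genes and both tissue comparisons 0 by edgeR (1435 and 1431 at an unadjusted p under 0.05), with 10 lists for the difference. Fits of only the groups compared gave 2 in lung and 2 in skin, and 3 against 3 lung libraries alone gave 5. Without the 4 libraries with the most gaps the counts were 6, 87, 31, 858 and 2171, Rel in skin was 0.0224, and the difference had 13 lists. Without the 2 Xist-positive libraries they were 439 in skin, 365 for the difference and 1044 between wild-type tissues, with 5 lists in skin. Without Rel-null skin 19 and 20 they were 55, 31 and 409 in skin, the difference and the Rel-null tissues, the last with 8 lists. An estimated correlation left 0, 1, 0, 4 and 2 lists, and fry 0, 1 and 3 in the first 3.

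Leaving out each library in turn gave 0 to 2 genes in lung, 0 to 421 in skin, 0 to 370 for the difference, 258 to 1050 between wild-type tissues and 410 to 1323 between Rel-null tissues. Rel ranged from -2.50 to -1.68 in lung and from -1.24 to -0.16 in skin. Called lists ranged from 8 to 14, 6 to 14, 4 to 15, 12 to 17 and 11 to 15.

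Some directions turned. With the leukocyte covariate, genes that turned between wild-type tissues were Chrna1 (-11.34), C1qtnf3 (-13.03), H2-D1 (0.47), Cdh2 (-0.16), Bst2 (0.57), Krt14 (-5.00), Krt6a (-4.28), Mmp12 (1.26) and Tnnc2 (-0.61). Between Rel-null tissues they were H2-D1 (0.18), Aldoc (0.51), Bst2 (0.48), Krt8 (-0.81), Pdpn (-0.29), Plk2 (-0.74) and Sesn1 (1.00). The test's direction turned for the TGF-beta list in skin (0.25), between wild-type tissues (-0.72) and between Rel-null tissues (-0.69). It also turned between wild-type tissues for NF-kappaB targets (0.42), interferon (2.41), integrins (-0.10), cholesterol (0.43), MHC class II (0.95) and keratinocytes (-0.76), and between Rel-null tissues for proliferation (0.0537), p53 (0.38), integrins (0.81) and MHC class II (1.30). The median kept its sign for the TGF-beta list in skin and between wild-type tissues, for NF-kappaB targets and cholesterol, and for proliferation, p53 and integrins between Rel-null tissues.

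For lists, what turned is the direction of camera's test, which can differ from the sign of the median. Contractile genes turned without Rel-null lung 7, with medians over single omissions from -0.49 to 0.46 in lung, -0.59 to 0.66 for the difference and -0.48 to 0.73 between Rel-null tissues. Without that library the list passed camera's threshold in each of these comparisons. Without wild-type skin 11, Cxcl5 (-1.61 to 4.82) and NF-kappaB targets (-2.84 to 1.13) between wild-type tissues turned. So did the test, but not the median, of the TGF-beta list (0.72) and skeletal muscle markers (-1.40) in skin. Their medians changed sign without 22 instead, to -0.21 and 8.24. Without 22, Ngfr (-3.20 to 13.47) and NF-kappaB targets in skin (0.00 to 3.49) did. Without the 4 libraries with the most gaps, Ltbp2 (2.74) and Slpi (4.44) turned in skin and Cxcl5 (-1.58) and Slpi (-2.69) between wild-type tissues. So did the lists of contractile genes in lung (-0.55), interferon in skin (-0.82) and for the difference (-0.63), and NF-kappaB targets between wild-type tissues (-2.15). Only the test turned, and the median kept its sign, for the TGF-beta pathway in skin (0.70) and for the difference (0.87) and for skeletal muscle in skin (-1.30). Without the Xist-positive libraries Ngfr (-3.49) and NF-kappaB targets in skin (0.00) turned. With 3 against 3 lung libraries contractile genes turned, at -0.30 alone and -0.29 with the skin libraries kept. Of the other values for named genes and lists, 9594 kept direction and side of the threshold, 318 newly passed it and 627 no longer did. A further 444 changed direction without passing the threshold before or after. The shallowest library, wild-type skin 22, limits what could be seen at low counts in skin.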

Other observations

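Macrophage genes were abundant in every lung culture after 14 days. Lyz2, encoding lysozyme, read 10701 ± 4344 CPM in wild-type (n = 5) and 12930 ± 5415 CPM in Rel-null lung (n = 4), near the level of Fn1 in wild-type lung, 11742 ± 3361 CPM. Leukocyte scores were 6.75 ± 1.01 and 7.35 ± 0.88 in lung against -0.91 ± 0.61 and 0.55 ± 0.40 in wild-type (n = 2) and Rel-null skin (n = 3).

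List tests between the Rel-null tissues were chosen only after results were seen. The labels were shuffled for the comparison of Rel-null skin with Rel-null lung. Of 35 splits of the 7 libraries, 1, the real one, gave as many genes (829, the highest other 597), so chance is unlikely to account for the gene count. As many lists were called in 11 of the 35, the real one included (13 with the real labels, 17 in the highest other). Most of the others still set most skin libraries apart from most lung ones. This count therefore cannot exclude chance for the number of lists.

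The mitochondrial share of counts ranged from 1.28% to 7.05%, highest in Rel-null skin 18.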
